A study of Mus musculus with 8 samples.

How the data were processed

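The submitters' notes name FastQC 0.11.2, STAR 2.4.0k, HOMER and the mouse genome mm10, and a stranded total RNA kit with ribosomal RNA removal. Nuclei had been taken through a sucrose cushion and the lysate incubated with anti-NONO or IgG beads. Per the file headers, the authors called peaks with HOMER in windows of 500 bp joined within 1000 bp, on both strands together, with each immunoprecipitate compared with its own input. A peak had to reach 2-fold over input and a tag threshold of 11 tags (8 in the IgG library). The deposited signal is the number of tags in the peak per 10000000 tags of the library, normalised by the authors with HOMER. The deposited fold is the authors' ratio of immunoprecipitate to input tags after scaling to equal library size, with input values as low as 0.4 tags. The deposited score is HOMER's own peak score, per the file headers, and the deposited p-value is the authors' Poisson p of immunoprecipitate against input, which was not used here. Score and fold served only to describe, rank and filter peaks within a list. Input libraries were used only through these values, and reads were not used here.

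Peak positions were laid on the GENCODE M21 annotation of mm10. Of peaks, 94.0% (fasted), 93.8% (2 h), 93.7% (10 h) and 94.3% (IgG) overlapped a gene body, against 48.7%, 48.5%, 48.3% and 48.6% after moving them by 5 Mb. Genes were 21951 protein-coding and 10155 non-coding genes, and a peak counted for every gene body it overlapped by 1 bp, since each peak is listed on the plus strand and strand could not be used. Over more than 1 gene lay 6.07% (fasted), 6.47% (2 h), 6.32% (10 h) and 6.95% (IgG) of peaks. An IgG-free peak is a NONO peak that no IgG peak overlaps by 1 bp. Each peak took 1 annotation class by its midpoint, with promoters set at 1000 bp upstream. Random placement kept peak widths, within the same gene or within the union of all lists, 20 times each. Gene lists were compared with 10000 random lists matched on gene length in 10 bins and on biotype, drawn from all genes with or without a peak. Independent lists would share n1 x n2 / N genes, with N the 11669 genes with a peak in any list.

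The comparisons, the 16 gene lists, the rule for named genes and the alternatives, except those named later as added, were fixed before the data were examined. The lists cover nuclear long non-coding RNAs, paraspeckle and other nuclear RNA-binding proteins, circadian clock, glucose uptake and glycolysis, gluconeogenesis, glycogen metabolism, lipogenesis and sterol synthesis, fatty acid oxidation and ketogenesis, insulin and nutrient signalling, secreted hepatocyte proteins and urea cycle, bile acid and xenobiotic metabolism, and markers of Kupffer cells, endothelium, stellate cells, cholangiocytes and of lymphocytes and erythroid cells. The rule names, per time, the 8 genes with the best score or fold among IgG-free peaks and the 8 with most IgG-free peaks. It names, per pair of times, the 5 genes on each side with the largest difference in peak number as a share of the list. It also names up to 4 members of each list with most peaks, and Neat1, Malat1, Nono, Sfpq, Slc2a2, Per1, Per2, Cry1, Fasn, Pck1 and G6pc whatever their value. Some genes that the rule names are not reported here. Score and fold were both taken where the rule allows either, and of the genes by fold only the first per time is named. No paired analysis was possible because each group has 1 library. In a self-test all 1500 planted overlaps among 5000 simulated peaks were found, and peak numbers of 3664 genes equalled a direct count. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.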

Results

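RNA immunoprecipitation with an antibody to NONO, an RNA-binding protein of paraspeckles (nuclear bodies built on the long non-coding RNA Neat1), was sequenced from liver nuclei of wild-type C57BL/6 mice aged 14 weeks. Livers were taken in the fasted state at zeitgeber time 10, 2 h after re-feeding at zeitgeber time 14 and 10 h after re-feeding at zeitgeber time 22, so feeding state and time of day differed together. Mice were kept in 12 h of light and 12 h of dark and had been fed in the dark phase only. The 8 libraries were 1 immunoprecipitate and 1 input at each of the 3 times, plus 1 immunoprecipitate with IgG and its input, whose feeding state the labels did not give. Each library was a pool of 2 experiments, so there was no replicate error for any difference between times and no p-value across genes was computed. The immunoprecipitates held 21032764 tags (fasted), 21091048 tags (2 h), 18275033 tags (10 h) and 18995778 tags (IgG).

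The fasted list held 38209 peaks over 29.7 Mb, the 2 h list 61737 peaks over 71.0 Mb and the 10 h list 50609 peaks over 44.7 Mb. The IgG list was of similar length, with 55946 peaks over 54.6 Mb. The share of library tags inside peaks was 11.6% in the fasted, 26.0% in the 2 h, 17.3% in the 10 h and 53.2% in the IgG library. A single IgG peak over Rn7sk, the gene of the abundant nuclear 7SK RNA (chromosome 9, 78175137 to 78175764), took 37.5% of the IgG library. Mean tag density in peaks was 39.1 (fasted), 36.7 (2 h), 38.7 (10 h) and 97.5 (IgG) normalised tags (tags per 10000000 tags of the library) per kb, and the IgG value includes the Rn7sk peak. The authors' fold over input had a median of 2.82, 3.13 and 2.84 in the NONO lists in order of time and 4.16 in the IgG list. At a stricter fold of 3.16 the lists shrank to 15171 (fasted), 30273 (2 h), 19882 (10 h) and 38846 (IgG) peaks.

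**Figure D1:**
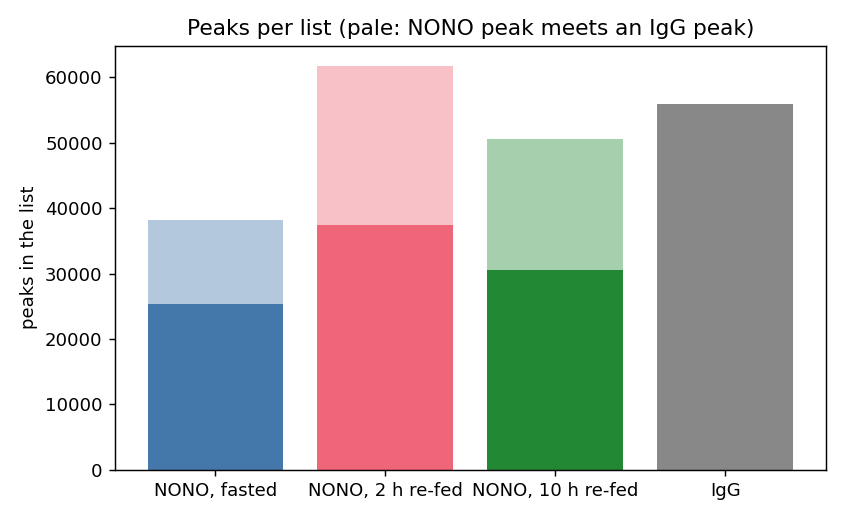
Number of peaks in each of the 4 lists (vertical axis, peaks; 1 library per bar), with NONO peaks that meet an IgG peak in the pale part of the bar. The part without an IgG peak holds 25317 (fasted), 37446 (2 h) and 30595 (10 h) peaks, and the IgG list is longer than the fasted and 10 h lists.

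Neat1, the long non-coding RNA that forms the core of paraspeckles, lay under the largest peak of the fasted and 2 h lists. In GRCm38 (mm10) coordinates the fasted peak spanned chromosome 19 from 5824790 to 5844759 with 30057.4 normalised tags and 4.33-fold over input, and the 2 h peak spanned 5820261 to 5844196 with 20421 normalised tags and 3.30-fold. At 10 h Neat1 carried 4 separate peaks, with 638.6, 2106.2, 1355.4 and 4126.9 normalised tags, the largest at 2.51-fold. No 1 of these is to be set alone beside the single peaks of the other times. The IgG library also had a peak there, from 5820510 to 5842543, with 23646.8 normalised tags (37825 per 10000000 tags outside the Rn7sk peak, above the fasted value) and 2.52-fold, so no Neat1 peak was free of IgG signal at any time. That fold was scaled to the whole library with the Rn7sk peak in it and was not rescaled. It is therefore not directly comparable with the NONO folds. Malat1, another abundant nuclear RNA, carried no peak in any of the 4 lists. Of the 11 nuclear long non-coding RNAs in the fixed list, 0 (fasted), 1 (2 h) and 2 (10 h) had a peak without an IgG peak over it, namely Kcnq1ot1 at 2 h and Rian and Snhg11 at 10 h, while 5 carried an IgG peak. Kcnq1ot1 lies within Kcnq1, and since both strands were pooled in peak calling its peaks cannot be assigned to either transcript.

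**Figure D2:**
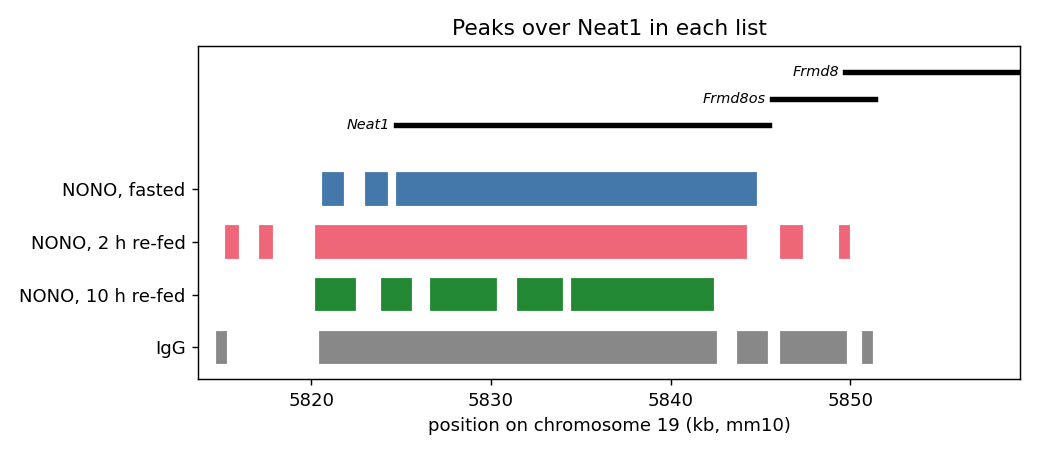
Map of the Neat1 locus on chromosome 19 (horizontal axis, kb, mm10), with every peak of each list as a coloured bar and the annotated genes as black lines. A single long peak covers Neat1 in the fasted and 2 h lists and in most of its length in the IgG list, and 4 peaks overlap it at 10 h.

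The IgG immunoprecipitate gives the background, with peaks called from a tag threshold of 8 in place of 11. The labels gave neither its feeding state nor its time of day, and the same IgG list filtered all 3 times. Where an RNA varies with either, a missing IgG peak may reflect low abundance in that library and does not establish specific binding. An IgG peak overlapped 33.7% of fasted (95% exact Clopper-Pearson interval 33.3 to 34.2), 39.3% of 2 h (39.0 to 39.7) and 39.5% of 10 h peaks (39.1 to 40.0). Such intervals cover counting error only. After random placement of IgG peaks within their own genes the overlap was 22%, 25.7% and 23.9%, and after placement within the regions covered by any of the 4 lists it was 37.7%, 40.7% and 39.1%, close to or above the observed shares. Those regions are made of the lists compared, so the second placement is no measure of overlap by chance. Among the most tagged NONO peaks, those over Acot12, Slc7a2, Cyp7b1 and Egfr met IgG peaks, whereas the fasted peak over Fbxo3 (7.89-fold) and the 10 h peaks over Eif4g2 (3.07-fold) and Kpna4 (2.53-fold) did not. The last 2 peaks also cover a small nucleolar and a small Cajal body RNA gene. Acot12, Slc7a2, Fbxo3 and Kpna4 stand outside the rule for named genes and were chosen after their values were seen. Peaks without an IgG peak numbered 25317 (fasted), 37446 (2 h) and 30595 (10 h). With every NONO list at its 38209 best-scoring peaks and the IgG list at full length the order turned, to 25317, 19246 and 20654. That cut left the fasted list whole and chose re-fed peaks by score. At 2 h IgG-free peaks had a median of 12.3 normalised tags, against 30.3 for peaks that met IgG. List length and the choice by score are therefore not separated in this turn.

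In the fasted list the best-scoring IgG-free peaks lay over mt-Nd1, on the mitochondrial genome, Abcc2 (a bile canalicular transporter), Tdo2 (tryptophan breakdown), Fcgr2b, Cps1 (urea cycle), Ppp1cb, Podn and Scp2, of which Podn and Scp2 overlap each other. The mitochondrial peak (174 to 2900) only reaches the edge of mt-Nd1, which starts at 2751. Most of it lies over mitochondrial ribosomal and transfer RNA genes, which were outside the gene set. The Tdo2 peak (chromosome 3, 81967115 to 81968029) had 1345 normalised tags and 5.57-fold in the fasted list and a matching peak had 241.3 normalised tags and 5.05-fold at 2 h, with no IgG-free Tdo2 peak at 10 h. Tdo2 did carry 1 peak at 10 h, with 235.8 normalised tags and 2.08-fold, which met IgG, and the gene had 4 IgG peaks. At 2 h the leading genes were Bhmt, Ahsg, Gm30505, Ghr, Aox3, Cyp2c70, Fcgr2b and Glud1, and at 10 h Alb, Fgb, Cyp3a25, Cps1, Ahsg, Gm30505, Eif4g2 and Slco1b2. The 2 h peak over Bhmt had 999 normalised tags and 2.09-fold over input. At 10 h the peaks over Alb and Fgb, which encode abundant plasma proteins, had 1710 and 1607.7 normalised tags, at 2.05-fold and 2.07-fold. Neither Alb nor Fgb had a fasted or 2 h peak. At the stricter fold Bhmt, Alb and Fgb had no IgG-free peak at any time. The difference between times for Alb and Fgb therefore rests on peaks of low fold. Fgb and Bhmt had no IgG peak. Alb had 2, the larger (chromosome 5, 90466142 to 90467151) with 2510.6 normalised tags close beside the 10 h peak (90465120 to 90465745). Gm30505 lies antisense to Ahsg and is not separable from it. By fold, the highest genes were Dennd2a at 49.25-fold (fasted), Dtd1 at 53.32-fold (2 h) and Egfem1 at 59.84-fold (10 h), each over an input of at most 2 tags.

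Peaks shared between times show how far the same regions were found again. Of fasted IgG-free peaks, 32.6% met a 2 h peak (95% exact interval 32.1 to 33.2) against 13.1% after placement in genes and 20.9% after placement in the regions covered by any list, and 28.3% met a 10 h peak (27.8 to 28.9) against 10.6% and 17.4%. Of 10 h IgG-free peaks, 35% met a 2 h peak (34.4 to 35.5) against 13.6% and 21.3%. Placed peaks that met an IgG peak were left out of the count of placed peaks, which inflates the excess over placement. Over all peaks, 51.2% of fasted peaks met a 2 h peak, against 28.5% after placement in genes and 42.1% in the regions covered by any list, and 28.9% of 2 h peaks met a fasted peak, against 18.2% and 29.7%, not above the latter. Regions covered by any list are made of the lists compared, so placement there is no measure of overlap by chance. Peaks met at both other times made up 14.1% of the fasted, 10.1% of the 2 h and 12.0% of the 10 h list, and peaks met at neither made up 53.2%, 59.9% and 53.7%. All 3 lists were filtered against the same IgG list, which is part of what they share.

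An IgG-free peak lay over 6481 genes in the fasted, 7815 in the 2 h and 7475 in the 10 h library, and 4908 of these genes carried one at all 3 times. Genes with a peak at 1 time only numbered 555 (fasted), 1145 (2 h) and 987 (10 h), and with equally long lists 1142, 644 and 835, the fasted number then being the highest. Protein-coding genes with a peak at all 3 times had a median length of 52.6 kb, those with a peak at 1 time only 17.5 kb (fasted), 16.5 kb (2 h) and 15.7 kb (10 h), and those with no peak in any list 9.51 kb. The fasted and 2 h libraries shared 5508 genes, against 4340 for independent lists. Peaks placed at random in genes reached 8412 (fasted) and 9766 (2 h) genes, more than observed, and shared 7240, so that number is no measure of sharing below chance. The fasted and 10 h libraries shared 5326, against 4152 for independent lists, and the 2 h and 10 h libraries 6070, against 5006. Of the genes with any NONO peak, 83.4% (fasted), 79.7% (2 h) and 80.8% (10 h) also carried an IgG peak somewhere in the gene, and leaving those genes out reduced the counts to 1169, 1714 and 1577, with 475 at all 3 times. With equally long lists 6481 (fasted), 5834 (2 h) and 6209 (10 h) genes remained. Only the 2 h and 10 h lists were cut, by score, so the order of the times depends on list length and on that choice of peaks.

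**Figure D3:**
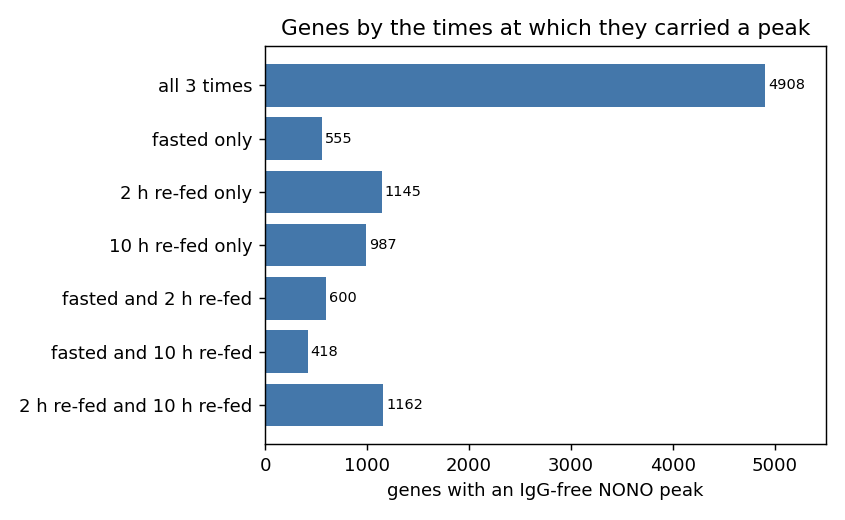
Genes with an IgG-free NONO peak (horizontal axis, genes) by the combination of times at which they carried one. Most, 4908 genes, carried a peak at all 3 times, and 555, 1145 and 987 at the fasted, 2 h and 10 h time only.

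The comparison of 2 h re-fed with fasted liver asks which transcripts NONO held soon after feeding. Gulp1, the gene of an engulfment adaptor (chromosome 1, 44551511 to 44796838), carried 35 IgG-free peaks at 2 h and none in the fasted, 10 h or IgG list. Zbtb7c carried 35 at 2 h against 0 fasted, Grm8 37 against 4, Snx29 44 against 9 and Esr1, the oestrogen receptor alpha gene, 52 against 17. On the fasted side Erbb4 carried 73 against 34 at 2 h, Wwox 47 against 9, Sugct 58 against 35, Carmil1 37 against 15 and Naaladl2 81 against 78 (0.320% and 0.208% of the list). Insr, the insulin receptor gene, carried 22 at 2 h against 9, and Ppargc1a, a coactivator of gluconeogenic genes with no IgG peak, 3 against 12. With equally long lists Gulp1 kept 11, Zbtb7c 15, Esr1 28 and Insr 20 peaks at 2 h, but Snx29 had 7, below its 9 in the fasted list, and Grm8 had 5 against 4, while at the stricter fold Insr had 6 against 5, Erbb4 29 at both times, and in fasted against 2 h liver Sugct 35 against 31, Carmil1 16 against 14 and Naaladl2 38 against 61. Peak number does not measure amount of signal, since windows within 1000 bp were joined into 1 peak. Over all peaks, with those that meet IgG, Sugct held 1385.98 (fasted) and 2225.99 (2 h) normalised tags. Naaladl2 held 3951.45 and 5664, so both had more tags at 2 h. Erbb4 (2155.11 and 1039.29), Wwox (954.83 and 95.29) and Carmil1 (1216.79 and 242.7) had more in the fasted list. No value has a replicate behind it, and antisense or overlapping transcripts under these genes (4930521E06Rik under Gulp1, for example) were not separated.

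Between fasted and 10 h re-fed liver, Slc4a4, a bicarbonate transporter gene, carried 24 and 62 IgG-free peaks, Robo1 5 and 36, Grm8 4 and 34, Sox5 19 and 52, and Magi1 43 and 81. Peaks were more numerous in the fasted list over Naaladl2 (81 against 27), Tmtc2 (50 against 10), Sugct (58 against 32), Tox (35 against 7) and Cadps2 (33 against 13). Sox5 had 213 and Magi1 104 IgG peaks, whereas Tmtc2 had 15 and Grm8 8. With equally long lists the 10 h counts were 51 for Slc4a4, 25 for Robo1, 30 for Sox5, 59 for Magi1 and 9 for Grm8. At the stricter fold Tox had 7 at both times, Tmtc2 15 against 7 and Slc4a4 20 against 30.

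Between 2 h and 10 h, Wwox carried 9 and 65 IgG-free peaks, Slc4a4 19 and 62, Erbb4 34 and 73, Magi1 56 and 81 and Camk1d 10 and 41. Naaladl2 (78 at 2 h and 27 at 10 h), Gulp1 (35 and 0), Esr1 (52 and 14), Zbtb7c (35 and 2) and Snx29 (44 and 10) had more at 2 h. Genes with many peaks at every time were Foxp1 (58 fasted, 84 at 2 h, 73 at 10 h), Vps13b (54, 62, 45), Lpp (49, 61, 60), Rabgap1l (54, 50, 50) and Fgfr2 (53, 87, 73). In equally long lists the 2 h count of each was the lowest or tied lowest, at 58, 35 and 54 for Foxp1, 54, 23 and 23 for Vps13b, 49, 23 and 39 for Lpp, 54, 18 and 34 for Rabgap1l and 53, 30 and 54 for Fgfr2. The annotated Fgfr2 body spans 2960900 bp and 48 other genes, and Gm20388 and Gm37240 overlap 120 and 12, so their counts belong to no single transcript. With equally long lists the 2 h counts were 0 for Wwox, 4 for Slc4a4, 6 for Erbb4, 12 for Magi1 and 1 for Camk1d, and at the stricter fold Camk1d had 9 at 2 h and 7 at 10 h and Magi1 48 and 45, the reverse order. Over all peaks Magi1 covered 221733 bp at 2 h and 168701 bp at 10 h, with 5107.71 and 5349.02 normalised tags. Wwox, Slc4a4, Erbb4 and Camk1d had more covered length and more tags at 10 h.

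Among 22 genes of the circadian clock, 12 (fasted), 16 (2 h) and 12 (10 h) carried an IgG-free peak, and 18 carried an IgG peak. Npas2, a paralogue of Clock (chromosome 1, 39193731 to 39363236), carried 23 peaks at 10 h (zeitgeber time 22), none fasted or at 2 h, and 1 in the IgG list. Its largest 10 h peak (chromosome 1, 39289140 to 39290698) had 66.2 normalised tags and 3.21-fold over input. Arntl, which encodes the activator BMAL1, carried 0 (fasted), 7 (2 h) and 13 (10 h). Per2, a repressor gene, carried 3 IgG-free peaks at 2 h (zeitgeber time 14) and none at the other times, and counted with peaks that meet IgG it had 2, 10 and 3 against 11 in the IgG list. Cry1 carried 4, 5 and 5, Per1 0, 2 and 1, Clock 4, 7 and 10, and Rora 13, 17 and 20 beside 88 IgG peaks. With equally long lists Npas2 had 21 peaks at 10 h, Arntl 0, 0 and 9 and Rora 13, 4 and 8, the reverse of its order between fasted and re-fed liver. At the stricter fold Npas2 had 6 at 10 h, Arntl 0, 7 and 4, Clock 1, 1 and 2, Cry1 3, 5 and 0, and Per1 none.

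**Figure D4:**
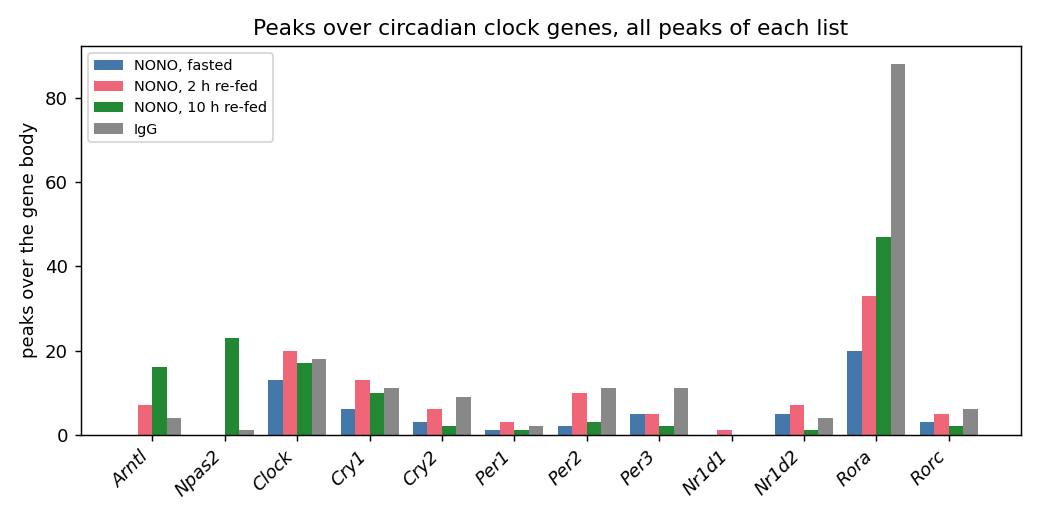
Peaks over the bodies of 12 circadian clock genes (vertical axis, peaks per gene; all peaks, 1 library per bar) in the 3 NONO lists and the IgG list. Npas2 stands at 23 at 10 h with none at the other NONO times and Arntl at 0, 7 and 16, while Rora has most peaks in the IgG list, 88.

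Of 24 genes of glucose uptake and glycolysis, 12 (fasted), 14 (2 h) and 13 (10 h) carried an IgG-free peak, beside 17 with an IgG peak. Slc2a2, the hepatic glucose transporter gene, had 1, 2 and 1, with its best-scoring IgG-free peak at 34.7 (fasted), 308.7 (2 h) and 81 (10 h) normalised tags over regions of 500, 1467 and 897 bp. Gckr had 3, 4 and 3, Pfkfb1 2, 3 and 4, and Gpi1 1, 5 and 1. In gluconeogenesis 8 (fasted), 12 (2 h) and 10 (10 h) of 17 genes carried one, with Pcx at 12, 7 and 8, Ppargc1a at 12, 3 and 9, Creb1 at 5, 8 and 10 and Got1 at 2, 7 and 1. Pck1 carried 0, 1 and 0 and G6pc none, although both encode major gluconeogenic enzymes. In glycogen metabolism 8, 8 and 10 of 16 genes did, with Phkb at 21, 22 and 14, Gbe1 at 16 at every time and Pgm1 at 5, 6 and 3. At the stricter fold Slc2a2 and Got1 had none at any time, Gckr 3, 0 and 0, Gpi1 1 at every time, Pcx 2, 3 and 4, Creb1 2, 0 and 0 and Phkb 8, 17 and 3. In equally long lists Phkb had 21, 11 and 12 and Pfkfb1 2, 1 and 3.

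In lipogenesis and sterol synthesis 18 (fasted), 21 (2 h) and 19 (10 h) of 29 genes carried an IgG-free peak and 26 an IgG peak. Acaca had 8, 7 and 12, Acacb 2, 9 and 6, Elovl5 2, 8 and 6, and Me1 6, 7 and 3, while Fasn, the fatty acid synthase gene, had none and 7 IgG peaks. In fatty acid oxidation and ketogenesis 17, 16 and 15 of 25 genes did, led by Cpt1a (8, 6, 3), Bdh1 (5, 5, 4, with no IgG peak), Hadhb (2, 5, 4) and Acsl1 (1, 4, 5). In insulin and nutrient signalling 19, 20 and 20 of 25 did, with Insr at 9, 22 and 10, Rictor at 9, 12 and 12, Egfr at 4, 10 and 12 and Ghr at 8, 8 and 10. In bile acid and xenobiotic metabolism 8, 16 and 14 of 22 did, or 12, 17 and 18 with peaks that meet IgG kept (Abcb4 4, 8, 6; Abcb11 3, 5, 8; Nr1i2 4, 6, 5; Cyp7b1 3, 3, 6). Secreted proteins and urea cycle gave 8, 14 and 13 of 27 (Fn1 6, 13, 11; Cps1 5, 6, 7; Cp 6, 3, 4; Apob 1, 7, 3). Among 24 nuclear RNA-binding proteins 16, 16 and 17 did, with Pspc1, a paraspeckle protein, at 5, 7 and 6, Hnrnpm at 3, 5 and 6, Cpsf6 at 1, 4 and 3, Ewsr1 at 2, 2 and 4, Nono itself at 1, 3 and 4 and Sfpq at 0, 1 and 2. At the stricter fold Egfr, Fn1, Apob and Sfpq had none at any time, Elovl5 had 1, 5 and 0, Acaca 4, 1 and 4, and Me1, Cpt1a, Bdh1, Hadhb, Acsl1, Ghr, Abcb4, Abcb11, Nr1i2, Cyp7b1, Cps1, Cp, Pspc1, Hnrnpm, Cpsf6, Ewsr1 and Nono at most 3 at any time, so their order between times rests on peaks of low fold. In equally long lists Rictor had 9, 8 and 7, Acacb 2, 2 and 1, Elovl5 2, 4 and 6 and Nono 1, 0 and 3. The numbers of IgG-free peaks do not measure amount of signal. Over all peaks, with those that meet IgG, Ghr held 4829.1 (fasted), 32526.2 (2 h) and 7146.2 (10 h) normalised tags. In the IgG list Ghr held 19478.7. The largest 2 h peak over Egfr, which met IgG, had 9296.4 normalised tags over 16417 bp.

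Glycolysis counts stood at the 97.6th (fasted), 98.5th (2 h) and 97.5th (10 h) percentile among 10000 random lists, gluconeogenesis at the 97.1st, 99.96th and 99.6th, lipogenesis at the 99.9th, 99.98th and 99.8th and RNA-binding proteins at the 100th, 99.99th and 100th. Among the same lists, which were matched on gene length, the fatty acid oxidation count stood at the 100th (fasted), 99.97th (2 h) and 99.8th (10 h) percentile and the bile acid count at the 63.6th, 99.98th and 99.8th. Insulin signalling stood at the 99.995th at each time, secreted proteins at the 80.9th, 99.8th and 99.6th, the clock at the 98.5th, 99.97th and 95.4th and glycogen at the 85.1st, 73.8th and 96.2nd. In the IgG library fatty acid oxidation, secreted proteins and the clock stood at the 99.995th percentile, bile acid, lipogenesis and RNA-binding proteins at the 100th, insulin signalling at the 99.985th, glycolysis at the 99.945th, gluconeogenesis at the 99.82nd and glycogen at the 99.3rd. Against random lists drawn from genes with a peak in any list, not matched on length, most percentiles were lower, with bile acid at 8.57 (fasted), 89.2 (2 h) and 69.6 (10 h), secreted proteins at 2.315, 27.155 and 22.035, the clock at 46.1, 70.7 and 18.0 and fatty acid oxidation at 99.03, 80.755 and 75.025. Glycolysis stood there at 74, 72.3 and 63.6, gluconeogenesis at 42.5, 85.1 and 57.2, lipogenesis at 82.2, 80.9 and 66.3, RNA-binding proteins at 94.9, 70.6 and 89.5 and glycogen at 65.4, 33.5 and 81.8. Insulin signalling stood at 99.59, 98.215 and 99.045. Only 10 (fasted), 18 (2 h) and 19 (10 h) of the 292 listed genes had a NONO peak and no IgG peak anywhere, against 135, 164 and 159 with an IgG-free peak.

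**Figure D5:**
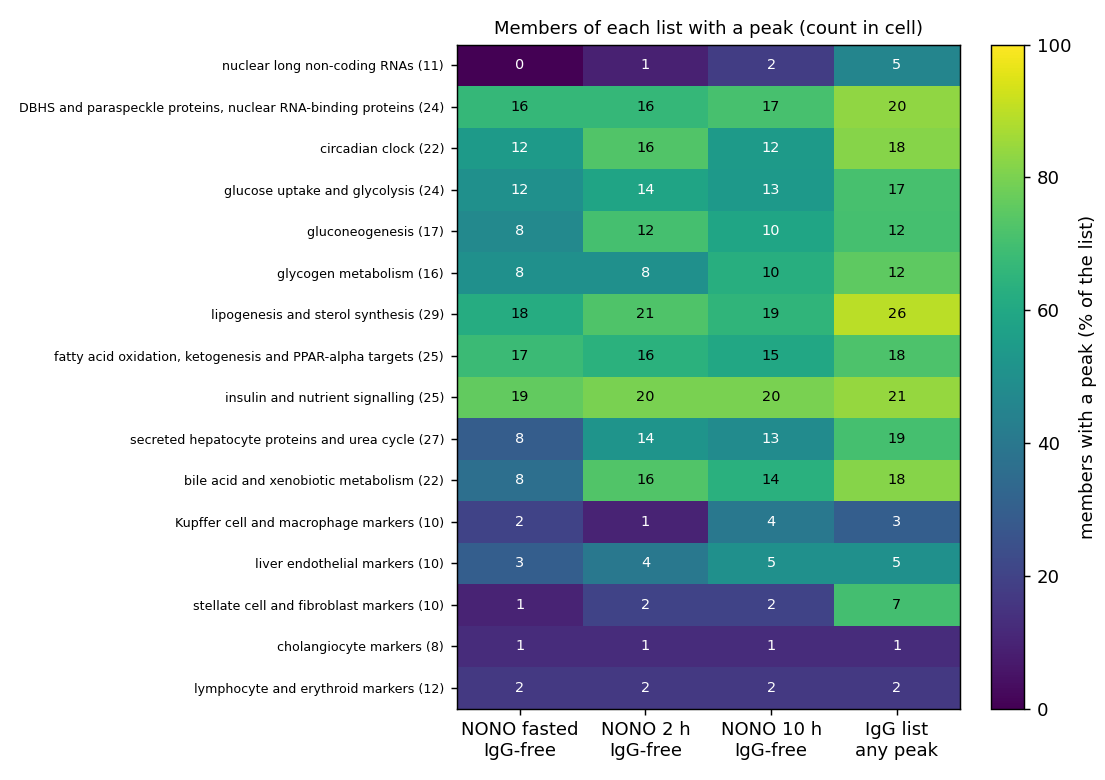
Members of each of the 16 gene lists with a peak (colour, % of the list, number of genes in brackets; count in each cell) for IgG-free NONO peaks at 3 times and for any IgG peak. Bile acid genes stand at 8, 16 and 14 of 22, and stellate markers at 1, 2 and 2 of 10 beside 7 in the IgG list.

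Liver nuclei also come from other cells. IgG-free peaks lay over 2 (fasted), 1 (2 h) and 4 (10 h) of 10 Kupffer cell markers (Adgre1, Timd4, Cd5l, Clec4f), 3, 4 and 5 of 10 endothelial markers (Stab2 8, 18, 16; Ptprb 6, 20, 10; Kdr 2, 6, 7; Cdh5 0, 0, 3), 1 at each time of 8 cholangiocyte markers and 2 at each time of 12 lymphocyte and erythroid markers (Ptprc 4, 4, 9; Alas2 3, 2, 1). Of 10 stellate cell and fibroblast markers 1, 2 and 2 carried one, Dcn and Reln, whereas 7 carried an IgG peak. With each peak counted for 1 gene Alas2 had none, at the stricter fold Ptprb had 2, 14 and 0 and Stab2 6, 7 and 5, and with equally long lists Reln had none and Dcn 1, 0 and 1. Reln had 104 peaks in the IgG list and 0, 1 and 6 IgG-free NONO peaks. Among length-matched lists the stellate count stood at the 9.26th (fasted), 18.0th (2 h) and 21.1st (10 h) percentile and in the IgG list at percentile 98.85.

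IgG-free peaks lay mostly in introns, 88.9% in the fasted (95% exact interval 88.5 to 89.3), 89.1% in the 2 h (88.8 to 89.4) and 88.6% in the 10 h library (88.2 to 88.9), with 91.2% in the IgG list (90.9 to 91.4). Introns make up 92.8% of the bodies of genes with a peak. That base leaves out promoters and intergenic sequence, whereas the peak shares are of all peaks, so the 2 are not directly comparable. The same holds for the shares of bases given below, and within gene bodies alone each peak share would be higher. In introns lay 22513 (fasted), 33362 (2 h) and 27103 (10 h) IgG-free peaks, and in exons of any class 901, 1227 and 1206. In 3' UTRs lay 2.52% (2.33 to 2.72), 2.14% (1.99 to 2.29) and 3.00% (2.82 to 3.20), against 0.940% of IgG peaks (0.862 to 1.02) and 2.96% of the bases of these genes. In coding exons lay 0.407%, 0.403% and 0.229%, against 0.756% of IgG peaks and 3.09% of bases. Fisher's exact test (two-sided, of libraries and not conditions) gave odds ratios for the 3' UTR of 2.72 (p = 4.18e-63), 2.30 (p = 1.25e-50) and 3.26 (p = 5.07e-107), each unadjusted. It set the IgG-free peaks of each NONO library against all IgG peaks and took peaks as independent. With all peaks of each NONO library the odds ratios were lower, at 2.04 (fasted), 1.70 (2 h) and 2.30 (10 h). Promoters held 0.691%, 1.34% and 1.09%, and intergenic sequence 6.83%, 6.29% and 6.38%. With no IgG removal the 3' UTR shares were 1.90%, 1.59% and 2.13%, still above the IgG share.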

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

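The tests of IgG depth, of shared host genes, of NONO depth, of gene length and of other cell types were chosen only after the result was seen. Small and mitochondrial RNA genes lay outside the gene comparisons, and some of their classes had more genes under a peak than in the IgG list. The fasted list had a mitochondrial peak with 20306.9 normalised tags over 2 mitochondrial ribosomal and 2 mitochondrial transfer RNA genes and mt-Nd1 (M, 174 to 2900, 2.09-fold), where the IgG list had none. Peaks lay over 13 ribosomal RNA genes at 2 h against 6 in the IgG list, over 5 small Cajal body RNA genes in the fasted and 5 in the 2 h list against 4, and over 62 (2 h) and 45 (10 h) small nuclear RNA genes against 41. Other classes and times were at or below the IgG list, with 36 (fasted), 50 (2 h) and 48 (10 h) small nucleolar RNA genes against 67, 28 small nuclear RNA genes in the fasted list, and 5 (fasted) and 6 (10 h) ribosomal RNA genes. The annotation holds 354 ribosomal, 51 small Cajal body and 1383 small nuclear RNA genes. These counts were not adjusted for covered length, which was 29.7 (fasted), 71.0 (2 h), 44.7 (10 h) and 54.6 Mb (IgG). Whether any of them exceeds the IgG list beyond counting error was not tested.

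The IgG list was longer than the fasted and 10 h lists and shorter than the 2 h list. Greater depth is argued against, since IgG tags outside the Rn7sk peak were 0.650 times those of the shallowest NONO library. Shared host genes alone are also argued against, since NONO peaks met IgG peaks at least 1.53 times as often as after placement in the same genes. A shared preference for parts of genes stays open. Placement within the regions covered by any list gave 37.7% (fasted), 40.7% (2 h) and 39.1% (10 h) against 33.7%, 39.3% and 39.5%. Since those regions are made of the lists compared, that placement cannot decide the question. A lower tag threshold may account for part, since 35676 IgG peaks reached the NONO threshold of 11, still close to the shortest NONO list of 38209. No biological explanation was tested.

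Peak numbers differed between the times, with the fasted list shortest. Lower depth is argued against, since the fasted library held 1.15 times the tags of the 10 h library. Feeding state and time of day cannot be told apart from differences between single libraries, with 1 library per state. Transcript abundance in the input cannot be told apart either. Across genes, the log2 ratio of peak numbers between 2 times was set against that of input density. The lowest Spearman rho was 0.117, between the bounds set for either reading, and genes are not independent replicates. Only genes with at least 3 shared peaks at both times entered (1641 to 2469 genes per pair). Genes with NONO peaks at 1 time only, such as Gulp1 and Npas2, were therefore not covered.

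Stellate cell markers were found in the IgG list. Gene length alone is argued against by the percentile of 98.85 among length-matched lists, which is the value already given above and no separate test. Those random lists include genes without a peak. In the IgG library the metabolic lists stood from the 99.3rd (glycogen) to the 100th percentile, so the value does not single out stellate markers. More RNA of every non-hepatocyte type would put markers of the other 4 cell-type lists in the IgG list more often than in each NONO list. Of these 40 markers 11 had an IgG peak and 8 (fasted), 10 (2 h) and 13 (10 h) a NONO peak, so only the 10 h list went against it. Most markers had no peak in any given list and the counts lie close together, so this test cannot decide the question. A second list of 30 stellate genes, which shares none with the fixed lists, had 22 members in the IgG list, at percentile 99.99, against 2 (fasted), 8 (2 h) and 7 (10 h), led by Ntm with 102 IgG peaks, Bmp5 with 29 and Rspo3 with 21. More stellate-cell RNA in the IgG library is a candidate explanation, as a hypothesis, although each IgG peak also exceeded its own input by 2-fold and the labels name no sort that would remove these cells.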

How the results depend on the processing

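The tests with IgG peaks widened by 1000 bp, with 1 gene per peak, with all biotypes and with no IgG removal for shared peaks were chosen only after the result was seen. By construction the stricter fold, equal lengths, at least 2 peaks and leaving out genes admit fewer peaks or genes and no IgG removal admits more, and any further cause was not tested. At a fold of 3.16 the lists held 15171 (fasted), 30273 (2 h) and 19882 (10 h) peaks, of which 12192, 22655 and 15269 were IgG-free. In NONO lists of 38209 peaks the IgG-free number was 19246 at 2 h, shared peaks were 5136 (fasted with 2 h) and 6146 (10 h with 2 h), and genes at 1 time only were 1142 (fasted) and 644 (2 h). Their shares at 2 h were 88.7% intron, 4.36% exon and 3.05% 3' UTR, and at 10 h 4.78% exon and 3.80% 3' UTR. With no IgG removal shared peaks were 19559 (fasted with 2 h), 15131 (fasted with 10 h) and 26752 (10 h with 2 h). Shares were then 90.6%, 90.3% and 90.1% in introns, 3.02%, 2.80% and 3.10% in exons and 1.90%, 1.59% and 2.13% in 3' UTRs, in order of time. Without genes that carry an IgG peak 1169, 1714 and 1577 genes were left, 475 at all times, 323 (fasted), 644 (2 h) and 550 (10 h) at 1 time, and 10, 18 and 19 list members. With at least 2 peaks per gene 3023 genes stood at all times and 309 (fasted) and 623 (10 h) at 1 time. A 50% overlap, widened IgG peaks, 1 gene per peak, all biotypes and removal of scaffolds kept each list-level count within 1.5 times. For 384 counts of named genes by time, beyond that limit equal lengths lowered 96, the stricter fold 217 and 1 gene per peak 12, while no IgG removal raised 177 and the 50% overlap 56. Random lists drawn only from genes with a peak and not matched on length, which changes both the pool and the matching, gave a lower percentile in 36 of 48 cases and a higher one in 9. Strand alternatives and leaving out a library could not be run, since each peak is listed on 1 strand and each group has 1 library.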

Other observations

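The tests and genes below were chosen only after the values were seen. Among genes with no IgG peak, Gulp1 had most NONO peaks, followed by Stau2, which encodes a double-stranded RNA-binding protein, with 14 (fasted), 10 (2 h) and 6 (10 h) peaks. Ppargc1a was next with 12, 3 and 9. Genes further down, not in order and with others left out, included Shq1, of snoRNP assembly, with 7, 10 and 3, Klhl15 with 4, 8 and 8, and Stk4, a Hippo pathway kinase, with 2, 10 and 4.

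The IgG list had its own genes. Ntm carried 102 IgG peaks and 0 (fasted), 0 (2 h) and 1 (10 h) NONO peaks, and Robo2 (50), Col14a1 (38), Pam (36) and Epha7 (31) carried IgG peaks and no NONO peak. Of 629 genes with at least 20 IgG peaks, 10 had no NONO peak. Of the IgG peaks, 21537 (38.5%, 95% exact Clopper-Pearson interval 38.1 to 38.9) met no NONO peak.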
